A study of Homo sapiens with 2 samples.

How the data were processed

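RNA associated with Ago1 was measured in HUVECs, primary endothelial cells of the umbilical vein pooled from 8 sources, after 24 h at 21% or 2% oxygen. Per the labels' protocols, cells were lysed in a buffer with 0.1% NP-40, Ago1 was precipitated with a monoclonal antibody and protein G beads, and RNA was extracted from the beads. The labelling kit primes RNA other than ribosomal RNA, with or without a poly(A) tail, per the labels' protocols. The biotin-labelled cDNA was hybridised to Affymetrix Human Gene 1.0 ST arrays, which have 1 colour and probe sets along the whole transcript. There were 2 samples, 1 array for each oxygen level, so the number of arrays limits the precision. Total RNA and a control precipitation are not used here.

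The deposited values are on a log2 scale and were made by RMA, per the submitters' processing notes. RMA corrects the background, usually equalises the probe distributions of the arrays and summarises probes into a probe set value. Its version, its settings and whether other arrays were normalised together with these are not given in the sources used here. The 2 deposited columns had medians of 4.62 (normoxia) and 4.63 (hypoxia) but different spreads, with SDs of 1.72 and 1.42 over 32321 probe sets, so the distributions of the deposited columns differed. Because the scaling within RMA is not known, a change in the total amount of precipitated RNA cannot be read from them.

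Probe sets were named through the platform annotation, in which 19158 had 1 gene symbol, 1388 several and 11775 none. A gene's value was the mean log2 value of its probe sets with exactly 1 symbol, and no gene was named from a probe set with several except in an alternative. Entrez identifiers matched 18344 of 18373 genes to the RefSeq gene table of GRCh38.p14. That table was used only for names, transcript class, genomic span and finding genes of the Y chromosome. No symbol needed updating. XIST, TSIX and Y-linked genes (31 genes) were left out. Background was the 95th percentile of 360 olfactory receptor genes on each array, which came to 4.98 in normoxia and 4.95 in hypoxia. A gene was used if its value exceeded it on at least 1 array. A fold is 2 to the power of the log2 difference. Where 1 of the values lay below background, the fold is a lower bound against that array's background and is written as at least that many fold.

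With 1 array per group no test between groups was run. Genes were counted at a log2 difference of at least 1 in size between the deposited values. Counts with values below background set to background, an alternative added after the data were seen, are given beside them. A gene list's median difference was set against the medians of 10000 random lists of the same size, drawn within 20 bins of mean log2 value. A list was called apart below percentile 2.5 or above percentile 97.5, as a description of these arrays. The two-tailed share of random lists as extreme was adjusted over the 25 lists by the Benjamini-Hochberg method. The percentile of a single gene is its rank in its own bin. A lowess trend of the difference on the mean value (fraction 0.3, 3 robust iterations, all genes) gave the differences relative to the trend.

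The gene lists fixed before the data were examined were silencing machinery, glycolysis and glucose uptake, other targets of hypoxia-inducible factors, angiogenic factors and receptors, and angiogenesis inhibitors. Further lists were endothelial identity, targets of let-7, of miR-103 and miR-107, of miR-210 and of miR-126, cell cycle and DNA replication, histones, endoplasmic reticulum and amino acid stress, and inflammatory activation. The rest were interferon response, immediate early genes, extracellular matrix, cholesterol synthesis, cytosolic ribosomal proteins, oxidative phosphorylation, mural cell and fibroblast markers, blood cell markers, epithelial markers and abundant nuclear noncoding RNAs. Small nucleolar RNAs, microRNA precursors and olfactory receptors were classes taken by symbol. A class of mitochondrially encoded genes had 0 genes among the named probe sets. Lists with fewer than 5 genes above background were given no percentile. Some genes belong to several lists, AGO1 among them.

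The genes named in the text followed a rule of size fixed at the same time. It took the 4 Argonaute genes, VEGFA, the 12 largest differences in each direction, the 3 largest in each direction among small nucleolar RNAs and among microRNA precursors, and the 2 highest and 2 lowest genes of each list. Small nucleolar RNAs, microRNA precursors, olfactory receptors and symbols starting with LOC were left out of the 12. Further members of a list are named as examples and were chosen after their values were seen.

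Alternatives were no filter, a filter on both arrays, the 99th percentile as background, centring on the median difference, quantile normalisation of the deposited columns and removal of the lowess trend. The others were the brightest probe set per gene, probe sets with several symbols, thresholds of 1.5-fold and 3-fold, random lists not matched on expression, and list means. Random lists matched on genomic span as well as expression were used for 7 lists and were added after the list medians were seen. The calculations were tested on simulated data made from the 9739 genes. Of 100 lists of 20 genes shifted by 0.5 log2 units, 94 were recovered, and 2 of 100 unshifted lists were called. These lists were drawn at random with shuffled differences, so the percentile rule sets the rate of unshifted calls. That rate does not cover lists whose genes vary together. Of 200 genes changed by 2 log2 units, 190 passed the 2-fold rule, as did 655 of 9539 unchanged genes. The unchanged genes carried the observed differences relative to the trend, shuffled among genes of like expression. The 655 therefore restates the observed spread and is not an error rate. The main count keeps the trend, unlike this simulation. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.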

Results

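Human umbilical vein endothelial cells (HUVECs), primary cells that line the vein of the umbilical cord, were pooled from 8 sources and kept for 24 h at 21% oxygen (normoxia) or at 2% oxygen (hypoxia). Argonaute 1 (Ago1), a protein that carries microRNAs to their target transcripts, was immunoprecipitated from each culture. The RNA recovered with it was hybridised to 1 array per oxygen level. The comparison asks which transcripts were more or less represented in the Ago1-associated RNA of hypoxic cells. Of 18373 named genes, 8672 (47.2%) lay above background on the normoxia array and 7870 (42.8%) on the hypoxia array. A total of 9739 genes lay above background on at least 1 array and 6803 on both, and these 9739 are the genes counted below. Their log2 values on the 2 arrays had a Pearson correlation of 0.793 across genes, which are not independent replicates.

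As a list, mRNAs of the RNA silencing and mRNA decay machinery, AGO1 among them, had lower differences than other genes of like expression. Differences are hypoxia minus normoxia in the Ago1-associated RNA. Transcripts of VEGFA, the main angiogenic growth factor, of its receptors FLT1 and KDR, and of the endothelial transcription factors ERG and FLI1 were each at least 2-fold lower, although VEGFA and KDR were less than 2-fold lower after each of 3 rescalings of the arrays. The angiogenic and endothelial lists that hold these genes were not called apart. Ribosomal protein mRNAs and small nucleolar RNAs, which guide the chemical modification of ribosomal and spliceosomal RNA, had higher differences than other genes of like expression. For ribosomal proteins the median difference was only 0.04, against -0.42 for random lists of like-expressed genes. They thus changed little on the deposited scale. Of the 9739 genes, 183 had a log2 difference of at least 1 and 811 one of -1 or less, so that 81.6% of the 994 were lower values in hypoxia. With values below background set to background, 47 were at least 2-fold higher and 472 at least 2-fold lower. This split depended on the scaling of the arrays. It was 337 higher and 334 lower (49.8% lower) after a smooth trend of the difference on the mean value was removed, 317 and 380 (54.5% lower) after quantile normalization of the deposited columns, and 469 and 259 (35.6% lower) after centring. The median difference, hypoxia minus normoxia, was -0.30 log2 units over the genes above background, and 0.17 over the genes below it. Of the genes above background, 70.0% had lower values in hypoxia, and counts of lower members in a list are to be read against that share. Differences are therefore also given relative to the trend, and each gene list is set against random lists of like-expressed genes. With 1 array per oxygen level the differences have no replicate check, so no p-values are given and the number of arrays limits the precision. Total RNA and a control precipitation are not analysed here, so a value does not separate the amount of a transcript from its association with Ago1.

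**Figure D1:**
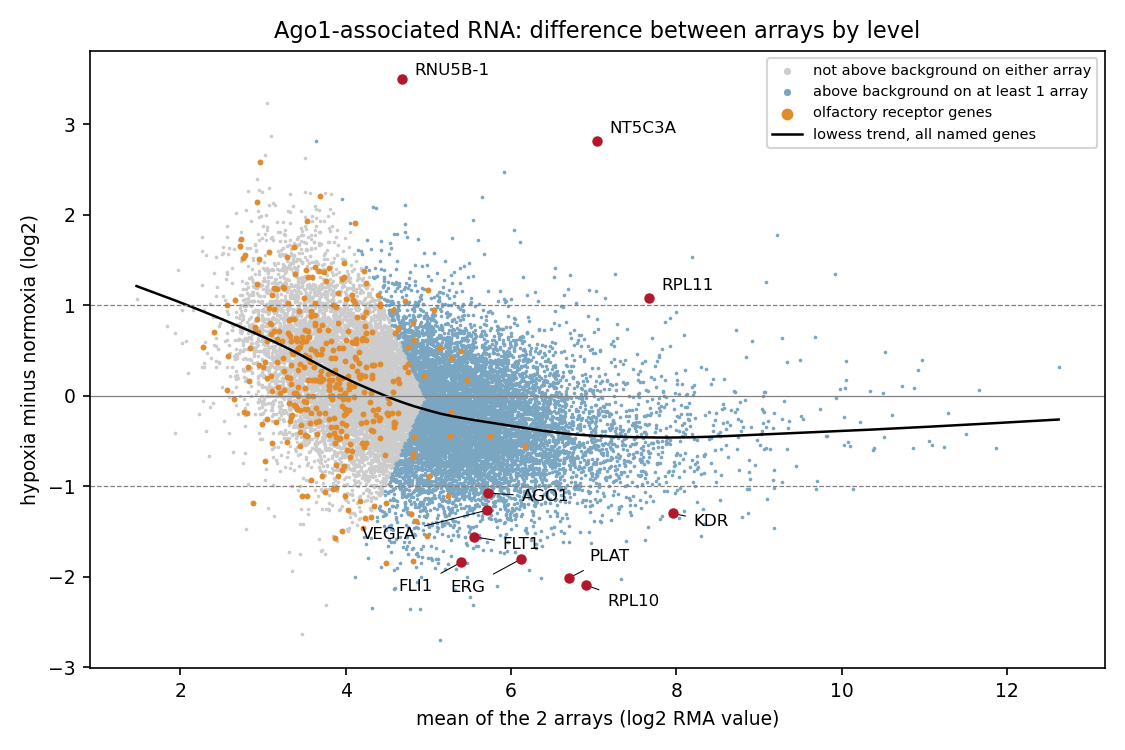
Log2 difference between the arrays (hypoxia minus normoxia) against the mean log2 RMA value of the 2 arrays for 18373 genes, with the smooth trend in black, dashed lines at 2-fold and 360 olfactory receptor genes in orange. Dim genes lay mostly above 0 and bright genes mostly below it; AGO1 (-1.08), VEGFA (-1.27) and ERG (-1.80) lay below the trend, and NT5C3A (2.81) and RPL11 (1.08) above it.

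AGO1, whose protein was precipitated, had a log2 value of 6.26 in normoxia and 5.19 in hypoxia, a 2.11-fold lower value. Relative to the trend its difference was -0.78, less than 2-fold, and it stood at percentile 5.13 among like-expressed genes. AGO2, which encodes the Argonaute able to cleave its target, differed by -0.57, and AGO3 by -0.55, or by -0.25 and -0.30 relative to the trend. AGO4 was not above background on either array. The silencing machinery list also holds genes of general mRNA deadenylation, decapping and decay, such as CNOT1, DCP2 and XRN1. It is therefore not specific to microRNA function. Of 28 mRNAs of the silencing machinery above background, 25 had lower values in hypoxia, and 23 did so relative to the trend. The 2 that were at least 2-fold lower were DDX6, a helicase of mRNA decay bodies (2.16-fold), and AGO1. Relative to the trend DDX6 differed by -0.84, so that no member was 2-fold lower by that measure. Other members were DGCR8, the partner of the microRNA processing enzyme Drosha (-0.97), and CNOT2, a subunit of the deadenylase complex (-0.96). TNRC6C, which encodes an Argonaute partner, was at least 1.80-fold lower. TARBP2, which encodes a partner of Dicer, differed by 0.72, CNOT8, a deadenylase, by 0.25, and DICER1 by 0.07. The median of the list was -0.70, against -0.30 for random lists of like-expressed genes. This put it at percentile 0.02 of the random lists. With the trend removed the median was -0.38, at percentile 0.04. It was -0.40 both after centring and after quantile normalisation.

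Glycolysis and glucose uptake, a set of genes that hypoxia-inducible factors activate, had 18 genes above background. Their median difference was -0.65 against -0.37 for the random lists, at percentile 2.27, and 15 of the 18 were lower. This call was lost in 3 of 10 alternative settings and against random lists also matched on genomic span (percentile 3.16). Of the 10, centring could not alter it. The adjusted share of random lists as extreme was 0.181. GPI, the isomerase that makes fructose phosphate, was 2.33-fold lower, and PKM, the last kinase of the pathway, was 2.07-fold lower. PFKM, a phosphofructokinase, was at least 1.44-fold lower, since its hypoxia value lay below background. LDHA, which makes lactate, differed by -0.84 and PGK1 by -0.74. SLC2A3, a glucose transporter, differed by 0.57. TPI1, an isomerase of the pathway, differed by 0.23 as the mean of its probe sets, but by -0.96 on its brightest probe set. Relative to the trend, 14 of the 18 remained lower and the median was -0.33. The other 25 targets of hypoxia-inducible factors had a median of -0.19, which turned to 0.07 relative to the trend, and stood at percentile 83.5. WSB1, part of a ubiquitin ligase, was 2.05-fold lower and NDRG1, a stress-response gene, differed by -0.98. BHLHE40, a transcriptional repressor, differed by 0.64 and JMJD6, a hydroxylase, by 0.35. ADM, which encodes the vasodilator adrenomedullin, differed by -0.50 and ANGPTL4 by 0.19.

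Of 34 angiogenic factors and receptors, 31 had lower values in hypoxia, where 70.0% of all genes above background did. Relative to the trend, 25 were lower. VEGFA had a log2 value of 6.34 in normoxia and 5.08 in hypoxia. It was 2.40-fold lower, differed by -0.97 relative to the trend and stood at percentile 1.44 among like-expressed genes. The VEGF receptor gene FLT1 was at least 2.59-fold lower and KDR, another receptor gene, 2.46-fold lower. Relative to the trend FLT1 differed by -1.29 and KDR by -0.84. The co-receptor gene NRP1 was 2.04-fold lower, but differed by -0.60 relative to the trend. APLN, which encodes the peptide apelin, was 2.51-fold lower and PDGFB, a growth factor that recruits mural cells, 2.01-fold lower, or -0.93 and -0.68 relative to the trend. DLL4, a Notch ligand of tip cells, differed by 0.10 and VEGFB by 0.09. The median of the list was -0.54 against -0.35 for the random lists, at percentile 3.24, which was not called apart, at percentile 7.56 with the trend removed and at percentile 5.15 with random lists also matched on genomic span. It was called lower in 5 of 10 alternative settings, of which centring could not alter the call. The 14 angiogenesis inhibitors had a median of -0.50, at percentile 12.7. Among them FOXO3, a transcription factor, differed by 0.87 but by 0.07 once probe sets shared with other genes were counted. SPRY2, an inhibitor of growth factor signalling, was at least 1.30-fold lower. SEMA3F, a repellent guidance ligand, differed by -0.94 and SPRY1 by 0.14.

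The 28 endothelial identity genes as a list did not stand apart, with a median of -0.38 at percentile 48.6, but its extremes were wide. ERG, an ETS transcription factor of endothelial cells, had values of 7.03 and 5.22 and was 3.49-fold lower. FLI1, a related factor, was at least 2.58-fold lower. Relative to the trend they differed by -1.45 and -1.59. KLF2, which responds to shear stress, differed by 0.40 and TAL1 by 0.18. Markers of other cells were set beside these. The 6 mural cell and fibroblast markers above background stood at percentile 75.2, with CNN1, a smooth muscle protein, at least 1.46-fold lower, RGS5 at -0.73, DES at 0.22 and COL1A2 at 0.20. The 5 epithelial markers stood at percentile 57.4, with MUC1 at least 1.14-fold lower, KRT19 at least 1.15-fold lower and KRT8 at -0.05. KRT18 differed by -0.19, or by 0.33 with probe sets of several genes counted. Only 3 blood cell markers lay above background, too few for a percentile: PPBP was at least 1.05-fold lower, CD68 differed by -0.22 and CD14 by 0.09.

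**Figure D2:**
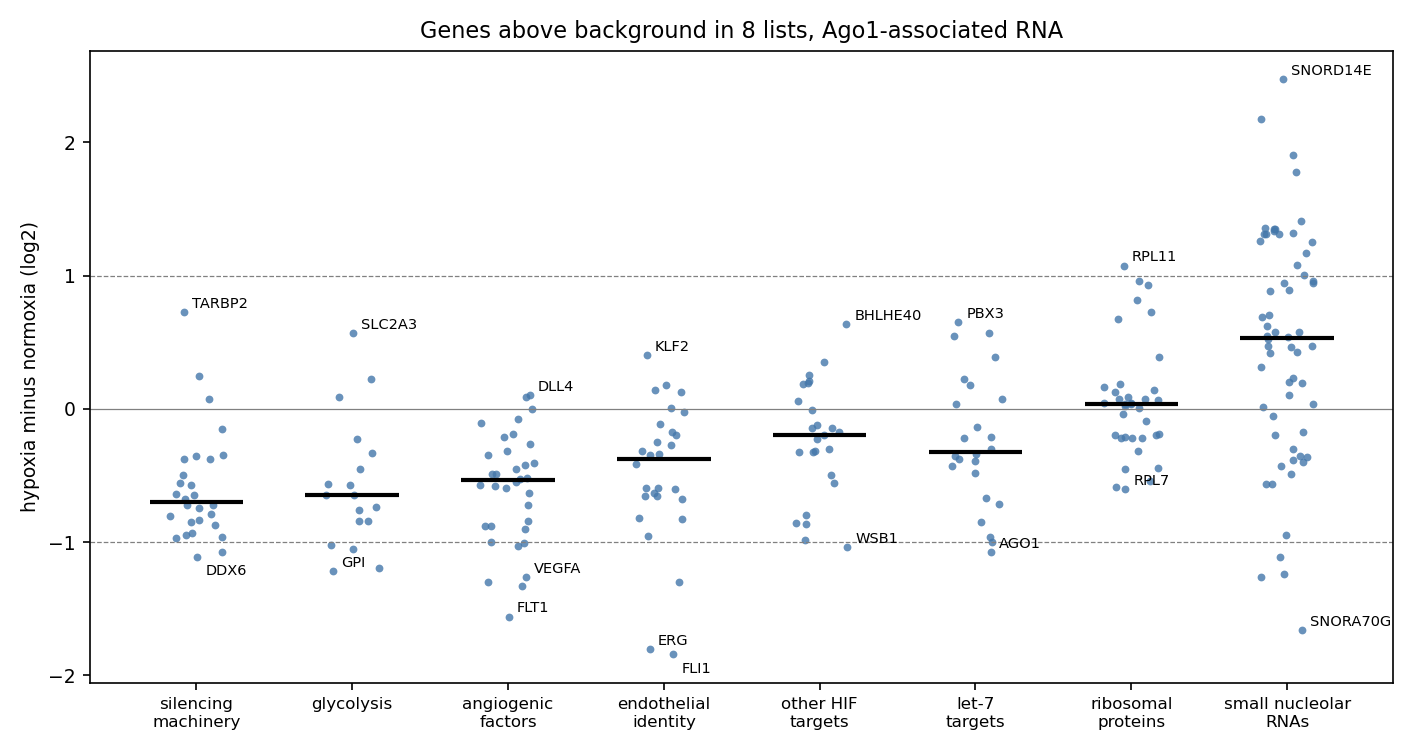
Log2 difference (hypoxia minus normoxia) of each gene above background in 8 of the gene lists, with the list median as a black bar and dashed lines at 2-fold. The silencing machinery had a median of -0.70 and small nucleolar RNAs one of 0.54; relative to the trend the median of other hypoxia-inducible factor targets was 0.07 and that of let-7 targets 0.00.

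Published targets of 4 groups of microRNAs were listed because Ago1 carries microRNAs to such transcripts. The 24 let-7 targets had a median of -0.32, against -0.33 for the random lists, at percentile 53.0, and of 0.00 relative to the trend. AGO1, itself a let-7 target, was the lowest, followed by PLAGL2, a transcription factor, at -0.997. PBX3, a homeobox factor, differed by 0.65, and E2F5, a cell cycle repressor, was at least 1.22-fold higher. The 10 targets of miR-103 and miR-107 stood at percentile 72.7, with a median of -0.21. It was 0.09 relative to the trend, but -0.72 with the stricter background (percentile 8.19), so its direction was not settled. DAPK1, a death-associated kinase, was at least 1.96-fold lower in that list and RAB1B, a GTPase of vesicle transport, was 2.41-fold lower. DICER1 differed by 0.07, and CDK6, a cell cycle kinase, was at least 1.19-fold higher. The 15 targets of miR-210, the microRNA most closely tied to hypoxia, had a median of -0.40, at percentile 26.8, which was -0.90 with the stricter background (percentile 4.21) and -0.09 after centring. In that list RAD52, a DNA repair gene, was at least 1.74-fold lower, FGFRL1, a growth factor receptor, was 2.03-fold lower, APC was at least 1.26-fold higher and EFNA3 at least 1.26-fold higher. The 10 targets of miR-126, an endothelial microRNA, had a median of -0.64 at percentile 2.94, or at percentile 2.37 with the trend removed, which would be called lower. TOM1, a trafficking adaptor, was 2.29-fold lower, LRP6, a Wnt co-receptor, differed by -0.95, PLK2 by -0.00, and DLK1, a Notch-like ligand, was 2.10-fold higher.

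Ribosomal protein mRNAs were the coding group that differed most from genes of like expression in the higher direction. The 36 of the fixed list had a median of 0.04 against -0.42 for the random lists, at percentile 100, and 31 of 36 lay above the trend. With the brightest probe set per gene the median was -0.04, at percentile 99.98. RPL11 was 2.11-fold higher, RPL23 at least 1.47-fold higher, RPS24 differed by 0.93 and RPL27 by 0.82. RPL7 differed by -0.60. RPL13 differed by -0.58, but by 0.27 on its brightest probe set. RPL10, which was not in the fixed list, was 4.27-fold lower, with a difference of -2.10, or of -1.17 with probe sets of several genes counted. The 21 nuclear-encoded genes of oxidative phosphorylation stood at percentile 48.8 with a median of -0.35. ATP5F1B, a subunit of ATP synthase, was 2.64-fold lower and NDUFS1, of complex I, at least 1.38-fold lower. COX7C was at least 1.33-fold higher, and NDUFB3 had a difference of 1.61 but reached background only just on the hypoxia array.

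Small nucleolar RNAs had 60 members above background, with a median of 0.54 against -0.35 for the random lists, at percentile 100. With values below background set to background, 10 were at least 2-fold higher and 3 at least 2-fold lower, and the median was 0.21 against -0.21, still at percentile 100. Of the 60, 47 lay above the trend. SNORD14E was at least 4.50-fold higher, while SNORD116-1 and SNORD78 were at least 1.04-fold and 1.01-fold higher, since their normoxia values lay below background. SNORD74 was 2.39-fold lower, SNORA67 at least 2.08-fold lower and SNORA70G at least 1.30-fold lower. The 53 microRNA precursor genes, of which 46 are annotated as microRNAs and the others as host transcripts, had a median of -0.02 that turned to 0.21 relative to the trend. They stood at percentile 99.4, but at percentile 62.7 over precursors above background on both arrays. MIR320C1 and MIR125B1 were at least 1.18-fold and 1.22-fold higher, and MIR130B had a difference of 1.15 from a normoxia value below background. MIR339 was 2.55-fold lower, MIR31 at least 1.88-fold lower and MIR107 at least 1.25-fold lower. The 5 abundant nuclear noncoding RNAs split. RMRP and RPPH1, the RNA parts of RNase MRP and RNase P, differed by 0.46 and 0.42, MALAT1 by -0.75, and MEG3 was 2.55-fold lower. Their median was 0.20 at percentile 98.5, but their mean was -0.20. The percentile was 90.1 with the trend removed and 92.7 with values below background set to background.

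**Figure D3:**
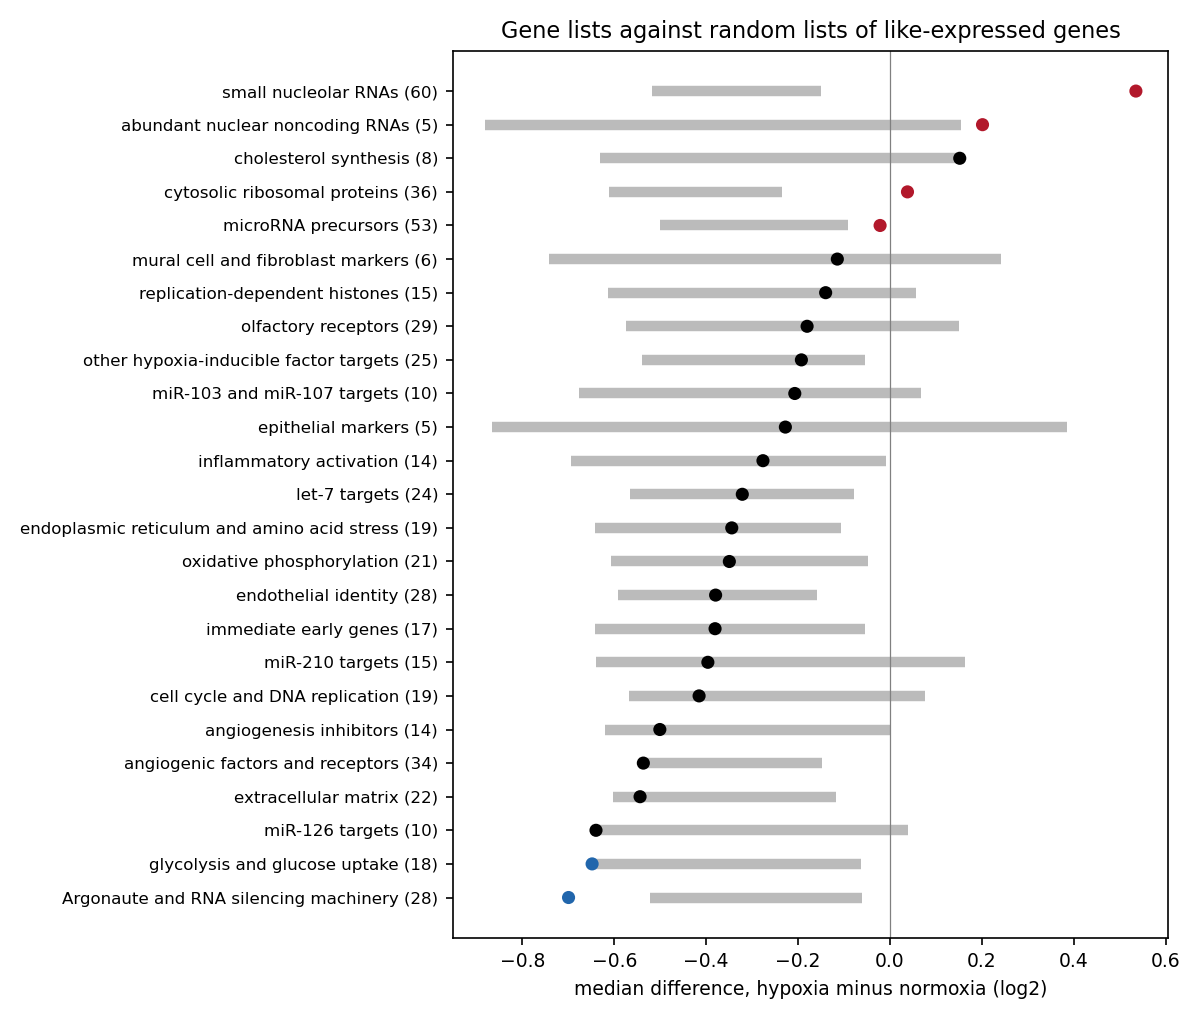
Median log2 difference (hypoxia minus normoxia) of each gene list with at least 5 genes above background (points, gene numbers in brackets), against the range that holds 95% of 10000 random lists of like-expressed genes (grey bars). Blue points were called lower than the random lists (silencing machinery at -0.70, glycolysis at -0.65) and red points higher, among them small nucleolar RNAs at 0.54.

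Other lists did not stand apart from the random lists. The 22 extracellular matrix genes had a median of -0.54, at percentile 7.03. The percentile was 0.95 with the trend removed, which would be called lower, but 16.5 with random lists also matched on genomic span. LOXL2, a collagen crosslinking enzyme, was 3.02-fold lower and NID1, a basement membrane protein, 2.33-fold lower. FN1, which encodes fibronectin, was 2.04-fold lower, MGP differed by 0.80 and COL5A1 by 0.10. The 8 cholesterol synthesis genes had a median of 0.15 at percentile 97.3, or 97.7 with the trend removed, which would be called higher. TM7SF2 was at least 1.43-fold higher, IDI1 differed by 0.43, SREBF2 by -0.44, and LSS was at least 1.36-fold lower. The 19 cell cycle genes had a median of -0.42, against -0.26 for the random lists, with MCM7, a helicase subunit, at least 1.53-fold lower, TOP2A at least 1.75-fold lower, CDC20 at 0.74 and GINS2 at 0.72. The 15 replication-dependent histone mRNAs stood at percentile 82.4, or 99.9 without a filter on low values, with H1-1 at least 1.83-fold higher, H2AC11 at least 1.32-fold higher, H1-4 at -0.77 and H4C8 at least 1.47-fold lower.

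Stress and signalling lists lay within the random lists as well. The 19 genes of endoplasmic reticulum and amino acid stress stood at percentile 60.0. CHAC1, which degrades glutathione, was 3.81-fold lower and PHGDH differed by -0.81, while DDIT3, a stress-induced transcription factor, differed by 0.79 and HERPUD1 by 0.73. The 14 inflammatory genes stood at percentile 71.3, with ICAM1, a leukocyte adhesion receptor, at -0.85 and CXCL8, a neutrophil chemokine, at 0.60. IRF1 was at least 1.13-fold lower and F3, which encodes tissue factor, at least 1.10-fold higher. The 17 immediate early genes stood at percentile 47.6, with DUSP1 at -0.87, ZFP36 at least 1.54-fold lower, JUND at 0.27 and EGR3 at least 1.02-fold higher. Only 4 interferon response genes lay above background, too few for a percentile: IFI6 differed by -0.66, ISG15 by -0.50, OAS1 by 0.30 and IRF7 by 0.07. The 29 olfactory receptors above a background that was set on this family stood at percentile 73.7. In all, 6 of 25 lists were called apart, against 1.25 expected for lists of randomly drawn genes. The lists share members, and genes of 1 list can vary together between any pair of arrays. The excess and the adjusted shares therefore describe these arrays and do not measure an effect of oxygen. For 3 of them, the silencing machinery, the ribosomal proteins and the small nucleolar RNAs, the adjusted share of random lists as extreme was at most 0.05.

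The largest single differences mostly involved a value below background on 1 array. Among the 12 genes with the largest lower values, RPL10 alone was above background on both arrays. NME2, a nucleoside diphosphate kinase, was at least 3.82-fold lower and PSMA6, a proteasome subunit, at least 3.35-fold lower. PMS2P1, a pseudogene, was at least 3.16-fold lower, and differed by -1.05 with probe sets of several genes counted. KRTAP10-11, a hair keratin-associated gene, was at least 2.89-fold lower, COG5, of a Golgi tethering complex, at least 2.72-fold, ZNF587 at least 2.19-fold and TMTC4 at least 2.01-fold lower. CDK11A, MST1, VPS52 and ARHGAP26 had bounds from 1.45-fold to 1.92-fold lower. Among the 12 with the largest higher values, NT5C3A, a pyrimidine nucleotidase, went from 5.63 to 8.44 and was 7.02-fold higher. CATSPER2P1, a pseudogene, was 3.56-fold higher. ZNF594 was at least 3.40-fold higher and RNU5B-1, a U5 spliceosomal RNA, at least 2.74-fold higher. PRSS3P2, a trypsinogen pseudogene, was at least 2.87-fold higher, but differed by 0.03 with probe sets of several genes counted. BIVM, LINC02877, ANAPC10, RDM1, EOLA1-DT, SCGN and ZNF208 had bounds from 1.05-fold to 1.73-fold higher. The unbounded difference of ZNF208 was 2.82, or 4.97 on its brightest probe set. Of genes above background on both arrays, 32 were at least 2-fold higher and 378 at least 2-fold lower. Chosen after the values were seen, the lowest of these included SHISA5, a p53-induced gene (4.06-fold), TRMT112, a methyltransferase activator (4.05-fold), and PLAT, tissue plasminogen activator (4.04-fold). PGD, of the pentose phosphate pathway, was 3.33-fold lower and TNPO3, a nuclear import receptor, 3.32-fold lower.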

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

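The alternatives below were chosen before the data were examined, except setting values below background to background, which was added after the results were seen. In that setting 519 genes were at least 2-fold apart, 47 higher and 472 lower, and 5 lists were called apart, the nuclear noncoding RNAs at percentile 92.7 no longer among them. The number of genes with a log2 difference of at least 1 in size, 994, was 1872 without a filter on low values, 410 with values above background required on both arrays, 3474 at 1.5-fold and 120 at 3-fold. The 183 genes with higher values became 941, 32, 666 and 31 in those settings, 89 with the stricter background, 469 after centring, 317 after quantile normalisation and 337 with the trend removed. The 811 genes with lower values became 378 with background exceeded on both arrays, 259 after centring, 380 after quantile normalisation, 334 with the trend removed, 2808 at 1.5-fold and 89 at 3-fold. The filter and threshold settings alter the counts by construction, since they alter the genes admitted or the size required. Centring alters them by construction too, since it shifts all differences equally. Removal of the trend does as well, since it subtracts the typical difference at each level. Quantile normalisation gives both columns the same distribution, so a more even split is largely built in there too. Of 70 named genes with a log2 difference of at least 1 in size, 45 kept it under all 5 alternatives that alter gene values, and none of the 350 values changed sign. The lack of sign changes says little. Centring subtracts only the median difference of -0.30, which cannot reverse a difference of that size. Genes such as VEGFA and AGO1 kept the same value under both probe set alternatives. AGO1 differed by -0.77 to -1.08 and VEGFA by -0.96 to -1.27. The median of ribosomal proteins turned to -0.0417 on the brightest probe sets, and the mean of the abundant nuclear noncoding RNAs was -0.20. The median of microRNA precursors turned to 0.42 without a filter, 0.28 after centring, 0.21 both after quantile normalisation and with the trend removed, and 0.0767 with probe sets of several genes. The turn after centring follows from its construction, since the median difference of -0.30 is subtracted from every gene. The turn with the trend removed follows likewise, since the trend was negative at their level (median -0.25 for mean values of 5 to 6). For the other turns the cause was not tested. Over 10 alternatives the silencing machinery, ribosomal proteins and small nucleolar RNAs were called apart in every one, microRNA precursors in 8 and glycolysis in 7. Centring is counted among the 10, but it shifts all genes equally and so cannot alter a percentile. The abundant nuclear noncoding RNAs were called in 3. Angiogenic factors and extracellular matrix genes, not called at first, were called lower in 5 each and targets of miR-126 in 4. Histone mRNAs were called higher without a filter (median 0.38, percentile 99.9). No paired analysis was possible because each oxygen level has 1 array, and no array could be left out for the same reason. The alternative log2(value + 16) was not run because the deposited values are already logarithmic. Signal over background limits the rest, since 1869 genes exceeded background in normoxia alone and 1067 in hypoxia alone.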

Other observations

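The families in the next paragraph and all tests after it were chosen after the results were seen, and only the 2 tests of genomic span were written down before their own result was known. The oxygen level itself stays open as an explanation throughout, untested, because each level has 1 array.

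Spliceosomal small nuclear RNAs had the highest median among 20 gene families and transcript classes described. Of 9 above background, 8 had higher values in hypoxia, with a median of 1.16 against -0.36 for random lists of like-expressed genes. RNU12, part of the minor spliceosome that removes rare introns, was 3.26-fold higher. RNU5E-1 was 2.89-fold higher and RNU4ATAC, also of the minor spliceosome, 2.23-fold higher, whereas RNVU1-1, a U1 variant, differed by -0.79. The 223 long noncoding RNAs had a median of 0.01 at percentile 100. The 26 pseudogenes had one of 0.23 at percentile 99.99, and the 148 transcribed pseudogenes one of -0.07 at percentile 100. Every noncoding and pseudogene class described stood at percentile 99.25 or above. A shift above like-expressed genes was therefore not particular to small nuclear or small nucleolar RNAs. The 49 mitochondrial ribosomal proteins had a median of -0.03 at percentile 99.9, or 0.18 relative to the trend. All 53 cytosolic ribosomal protein genes found by symbol, with RPL10 among them, had a median of 0.03. Of 68 keratin-associated protein genes, which encode proteins of hair, 36 lay above background, and 31 of those had lower values in hypoxia. Their median was -0.91 against -0.34 for random lists. Such genes passed the filter about as often as genes in general (9739 of 18373). Passing it therefore does not show that a transcript was present. The 17 ETS transcription factors as a family stood at percentile 11.2 with a median of -0.50, although ERG and FLI1 were among the lowest endothelial genes. Of 4230 probe sets without a gene name above background, 743 had a log2 difference of at least 1 and 612 one of -1 or less. With values below background set to background, 324 were at least 2-fold higher and 417 at least 2-fold lower, so the balance depended on this choice. The widest were 7892732, from 1.09 to 7.10 (at least 4.32-fold higher), and 7895264, from 7.08 to 0.99 (at least 4.37-fold lower). The annotation used here does not tell whether control probe sets are among them.

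Most genes above background had lower values in hypoxia (70.0% of them). An intensity-dependent difference between the arrays is a candidate explanation. Olfactory receptor genes, which endothelial cells are not known to use, showed it as well, with a slope of the difference on the mean log2 value of -0.362 (95% bootstrap interval -0.489 to -0.241), against -0.241 for other genes. Such a slope is negative whenever values spread less on the hypoxia array, whatever the cause. Only 29 of the 360 olfactory receptor genes lay above background. The slope therefore cannot decide why genes above background were lower. A lower amount of most Ago1-bound mRNAs in hypoxia remains open too. Genes below background had a median difference of 0.171, but how RMA scaled these arrays to each other is not known, so this value cannot decide between the explanations.

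The differences of ribosomal protein mRNAs lay above, and those of silencing machinery mRNAs below, the differences of genes of like expression. Differences relative to the trend went from a median of 0.15 in the fifth of genes with the shortest genomic span to -0.16 in that with the longest, so genomic span could have produced both shifts. Against random lists matched on span as well as expression, the ribosomal proteins stayed at percentile 99.7 and the silencing machinery at percentile 0.05, which argues against genomic span as the whole cause, while transcript length was not tested and stays open. The silencing machinery stood at percentile 0.04 with the intensity trend removed. Its random lists were already matched on expression, so this is not a separate test of that trend. Sequence composition of the probes stays open, because keratin-associated protein genes, which have no known role in endothelium, had a median of -0.906 and probe sequences are not used here.

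The differences of small nucleolar RNAs lay far above those of genes of like expression. Relative to the intensity trend their median was 0.803, at percentile 100. The random lists were already matched on expression and share that trend, so this percentile is not a separate test of it. More nuclear RNA in the hypoxia sample stays open. The abundant nuclear noncoding RNAs had a median of 0.336 relative to the trend (SD over random lists 0.262), below the 0.803 of small nucleolar RNAs. Their members ranged from -0.97 (MEG3) to 0.92 (RMRP). Better recovery of RNAs without a poly(A) tail stays open too, because the values point both ways. Histone mRNAs had a median of 0.190 relative to the trend (SD 0.170), well below the 0.803 of small nucleolar RNAs. Without a filter, however, they stood at percentile 99.9. Spliceosomal small nuclear RNAs had a median of 1.48 relative to the trend, above that of small nucleolar RNAs. They are nuclear and lack a poly(A) tail, so they go with either explanation and cannot separate the 2. Recovery that favours short RNAs was not tested and stays open.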
